A study of Homo sapiens with 12 samples.

How the data were processed

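Total RNA of 12 established pancreatic carcinoma cell lines was hybridised to 1-colour Agilent whole human genome arrays, 1 array per line. Per the labels, 8 lines carry a loss of 8p11.22-ter, the part of the short arm of chromosome 8 from band 8p11.22 to its end, and 4 lines do not. Each line is a separate sample, so p-values measure the spread between lines, and no line was hybridised more than once. The arrays lie on 3 slides of 4 arrays. Slide 1 holds PANC-1, PK-1, KP-1-NL and AsPC-1, slide 2 holds MIA Paca2, SUIT-2, TCC-Pan2 and BxPC-3, and slide 3 holds KP4-1, PK-9, PK-45H and PK-59. AsPC-1, BxPC-3, PK-45H and PK-59 are the lines without the loss. Slides 1 and 2 were scanned on the same day and slide 3 on another.

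The deposited scanner files give spot intensity on a linear scale, per the file headers, as read by Agilent Feature Extraction. The file headers name version 9.5.3.1 of that program and the submitters' processing notes name version 9.1. The processed signal used here is the program's background-corrected intensity. The files also hold flags for spots well above background, saturated or outlying. The authors' series matrix holds log2 values. Set against the scanner files, each of its probes was centred on its own median over the 12 arrays, since the largest absolute row median was 5e-07. Its array offsets had a correlation of 0.99998 with minus the log2 median signal and of 0.675 with minus the log2 75th percentile, so each array appears to have been scaled on its median, from the values alone. Of its 41078 rows, 41000 matched a probe and 78 did not. The correlation with the scanner values was at least 0.993 on each array and positive, so its direction and scale are known, and the medians of its columns lay between -0.20 and 0.22.

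Each array holds 45015 spots, of which 1639 control spots were left out, leaving 41000 probes. Spots with an outlier flag were set aside, spots of 1 probe were averaged as log2 values, and each array's 75th percentile of the log2 processed signal was subtracted. Gene names came from the accession of each probe through a table of the GRCh38.p14 assembly, used for names and gene order only. The file headers name build hg18, so no coordinates are given. In all, 23958 probes were named, for 16557 genes, and 17042 probes kept their accession. The 63 probes of XIST, TSIX and genes of the Y chromosome were left out. A probe entered the tests when it was well above background on at least 4 of the 12 arrays, and the probe with the highest mean signal stood for its gene. This left 23351 features, of which 13537 were named genes and 9814 unnamed accessions. The 197 features with a missing value were left out of the set tests.

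The precision is limited by the number of arrays. Between 62.2% and 74.1% of the probes of an array were well above background, and no probe was saturated on any array. Where a gene's probe was not well above background on any array of a group, its fold is a bound. The bound sets the brighter group's mean against the mean over the dim group's arrays of the higher of the lowest signal well above background and the probe's own signal, and it is written "at least N-fold". The fitted log2 difference of a dim gene includes signals below background, and it can exceed the bound.

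Differences are 8p loss minus no 8p loss, on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The region was every gene of chromosome 8 from the p terminus up to and including ADAM2. The lists were tested with limma's camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry for the region. A level per line is the median over a list's genes of the log2 signal minus the gene's mean over the 12 lines. Levels and single genes were compared by an exact two-sided permutation test over all 495 splits of the 12 lines into 8 and 4. The slide-adjusted difference was tested by exact permutation within slides, 96 in number. Chromosome arms with at least 20 tested genes were compared in the same way, with each gene placed on an arm from its order and an approximate centromere. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

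The design, the 24 gene lists with 466 entries, of which 446 had a probe, the rule for named genes and most alternatives were fixed before the data were examined. The rule names DUSP4, the 10 region genes with the smallest p among those lower and the 3 among those higher, the 5 genes with the smallest p in each direction over all genes where none pass, and up to 4 genes of each list by smallest p. Every gene the rule picks is named. The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' matrix, no filter on dim probes, a filter on all arrays, the mean of a gene's probes, slide as a fixed or random block, the slide with 2 lines of each group alone, eBayes with trend and robust, array weights, a region ending at FGFR1, the mean over region genes, an estimated correlation, fry, a 2-fold threshold, a relaxed threshold of 0.1, and each line left out in turn. Normexp was run on the median spot signal, because the mean spot signal the plan named was not among the columns used here. A further 3 alternatives were chosen after seeing the data, namely averaging PANC-1 and KP-1-NL, leaving both out, and using slides 1 and 2 only.

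The fit was tested on simulated data for 8p loss against no 8p loss over 23154 genes. With 200 genes changed, it recovered 4.63% of genes changed 2-fold, 41.0% of those changed 4-fold and 78.8% of those changed 16-fold, with 4.7 false calls on average. A simulated shift of the region by -0.5 log2 was called by camera in 10 of 10 simulations and an unshifted region in 0. The genes were simulated independently of each other, while the real region had an estimated correlation of 0.153. The 0 therefore does not give camera's rate of false calls in these data.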

Results

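The expression of genes in 12 pancreatic carcinoma cell lines was measured on 1-colour Agilent arrays to find genes expressed less in lines that have lost 8p11.22-ter, the end of the short arm of chromosome 8. The loss is present in KP4-1, MIA Paca2, PANC-1, PK-1, SUIT-2, TCC-Pan2, KP-1-NL and PK-9 (8p loss, n = 8) and absent from AsPC-1, BxPC-3, PK-45H and PK-59 (no 8p loss, n = 4). Between 62.2% and 74.1% of the 41000 probes were well above background in the 8p loss lines and between 66.9% and 73.7% in the lines without the loss. The 75th percentile of the processed signal ranged from 908 to 1438 and from 1131 to 1312 in the same groups. PANC-1 and KP-1-NL, both with the loss and on slide 1, resembled each other more than any other pair. Their deviations from the gene means had a correlation of 0.717 over 21280 probes, against at most 0.261 for any other pair, and 6.62% of the probes differed over 2-fold. Many genes still differed between them, so both were kept as separate samples. That does not show the 2 lines to be independent of each other, and tests over 12 lines count them as 2. Averaged as 1 sample, they left the level of the 8p11.22-ter genes different by -0.71 between the groups (exact permutation p = 0.00909).

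The first comparison asked which genes of 8p11.22-ter were lower in the lines with the loss. Of 140 tested genes, 122 were lower and 18 higher, with a median log2 difference of -0.69 and quartiles of -1.17 and -0.29. The median was -0.43 with normexp correction, the smallest size under any alternative. FDFT1, which encodes squalene synthase of the cholesterol pathway, was 3.40-fold lower. Its log2 difference was -1.76 (SE 0.27), with levels of 2.29 ± 0.36 (SD, n = 8) against 4.06 ± 0.41 (SD, n = 4), and each of the 8 lines with the loss lay below every line without it (exact permutation p = 0.00202, the smallest the design allows). It was the only gene of the region past the limma threshold adjusted over the list alone (adjusted p = 0.00346), and it did not pass over all genes tested (limma adjusted p = 0.289). At an unadjusted p under 0.05, 34 region genes were lower and 0 higher. The call of FDFT1 ended using slide 3 only, at -1.62 (limma adjusted p = 0.287 over the list alone), and using slides 1 and 2 only, at -1.75 (limma adjusted p = 0.118), where 0 region genes passed. With slide as a fixed block 2 genes passed over the list alone, and with array weights 8 did.

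Other region genes had differences that did not pass limma's test over the list alone. BMP1, a procollagen protease, differed by -2.28, and ZNF395 and NPM2, a nuclear chaperone, both by -1.73. LONRF1 differed by -1.41, BIN3 by -1.19, ERICH1 by -1.11, DCTN6, a dynactin subunit, by -0.88, and VPS37A, a component of the ESCRT-I complex, by -0.79. Their limma p adjusted over the list alone lay between 0.0746 and 0.0976. BMP1, BIN3 and DCTN6 were lower in all 8 lines with the loss than in every line without it. In all 5 region genes were separated in this way downward and 1 upward, where chance gives 0.202% of genes in each direction. At least 2-fold differences were seen for 44 genes downward and 4 upward. The higher genes with the smallest p were LZTS1, FGFR1, a receptor tyrosine kinase, at 2.55, and LOXL2, a lysyl oxidase, at 1.99. LZTS1, the 1 gene separated upward, was not well above background in any line without the loss and was at least 2.13-fold higher, being well above background in 4 of 8 lines with it. None of the 3 passed (limma p adjusted over the list alone at least 0.229), and LOXL2 turned to -2.15 within slide 3. FGFR1, well above background in 2 of 4 lines without the loss, was 0.94 without PK-59 and LOXL2 0.11 without BxPC-3.

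DUSP4 in 8p12, a phosphatase that inactivates MAP kinases, was 8.27-fold lower in the lines with the loss. Its log2 difference was -3.05 (SE 0.94), from -0.71 ± 1.93 (SD, n = 8) against 2.33 ± 0.83 (SD, n = 4). The spread among the lines with the loss was wide. PANC-1 had the lowest level at -3.44, followed by MIA Paca2 at -2.51, KP4-1 at -2.21, KP-1-NL at -1.32 and PK-9 at -0.09. SUIT-2 at 0.90, PK-1 at 1.17 and TCC-Pan2 at 1.78 lay near AsPC-1, the lowest line without the loss, at 1.39. The highest levels were those of BxPC-3 at 2.62 and PK-59 at 3.32. The single value gave an exact permutation p of 0.0162, and 7 of the 8 lines lay below every line without the loss. Adjusted over all genes, limma's p was 0.489, and over the list alone 0.1002, so DUSP4 did not pass in the test across genes. With slide as a block the difference was -3.07 (exact permutation within slides, p = 0.0417). Within slides 1, 2 and 3 it was -2.59, -2.56 and -3.81.

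**Figure D1:**
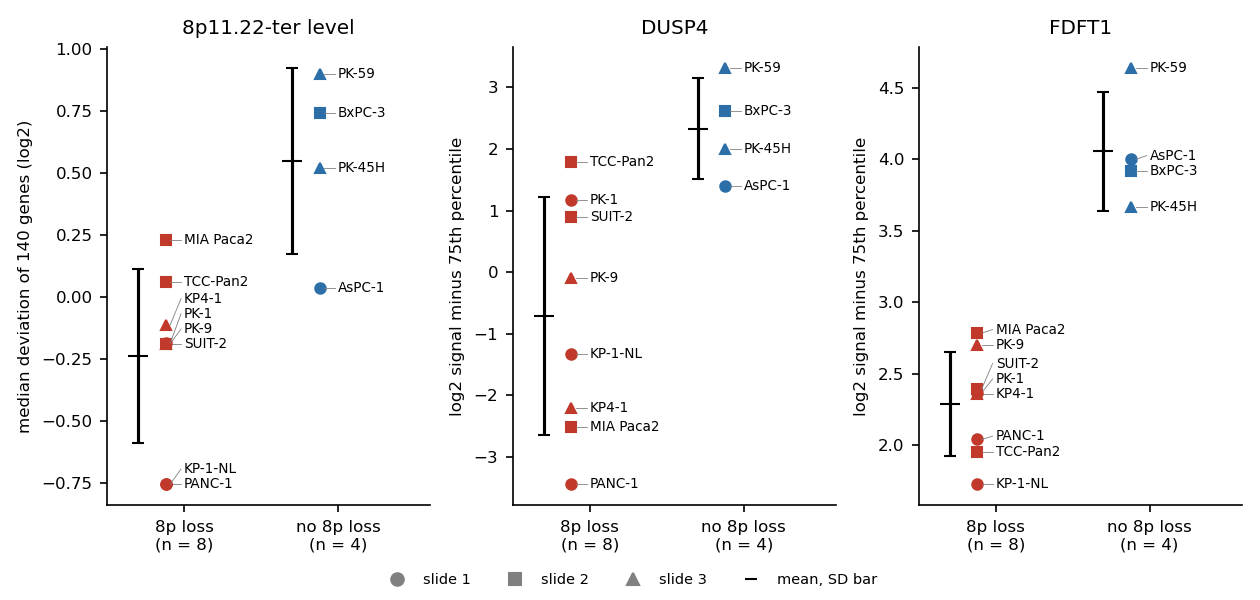
Level of the 8p11.22-ter genes (left; median deviation of 140 genes, log2), of DUSP4 (middle) and of FDFT1 (right; both log2 signal minus the array's 75th percentile) in each cell line, with symbols for the slide and bars for the mean and SD of 8 lines with and 4 lines without the loss. FDFT1 separates the groups completely, while TCC-Pan2 overlaps AsPC-1 for DUSP4.

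As a group, the region's genes were lower in the lines with the loss. The level per line was -0.24 ± 0.35 (SD, n = 8) against 0.55 ± 0.38 (SD, n = 4), a difference of -0.79 (exact permutation p = 0.00606). It was lowest in PANC-1 and KP-1-NL, both at -0.76, and highest in PK-59 at 0.90, and 6 of the 8 lines with the loss lay below every line without it. MIA Paca2 at 0.23 and TCC-Pan2 at 0.06 lay above AsPC-1 at 0.04. With slide as a block the difference was -0.74 (exact permutation within slides, p = 0.0104, the smallest that test can give), and within slides 1, 2 and 3 it was -0.60, -0.71 and -0.86. Using slides 1 and 2 only it was -0.62 (exact permutation p = 0.143), and using slide 3 only -0.71 (exact permutation p = 0.333). Limma's camera gave p = 8.5e-17 for the 138 region genes without missing values against all other genes, and p = 0.0208 with an estimated correlation, whose value was 0.153, while fry, a rotation test of the set against no change rather than against other genes, gave p = 0.00729. Next to the region, the 21 tested genes of proximal 8p differed by -0.46 in level (exact permutation p = 0.198), with -0.46 under the slide block (p = 0.0104, exact permutation) and -0.73, -0.12 and -0.50 within slides 1, 2 and 3. The 293 genes of 8q differed by -0.06 (exact permutation p = 0.679).

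**Figure D2:**
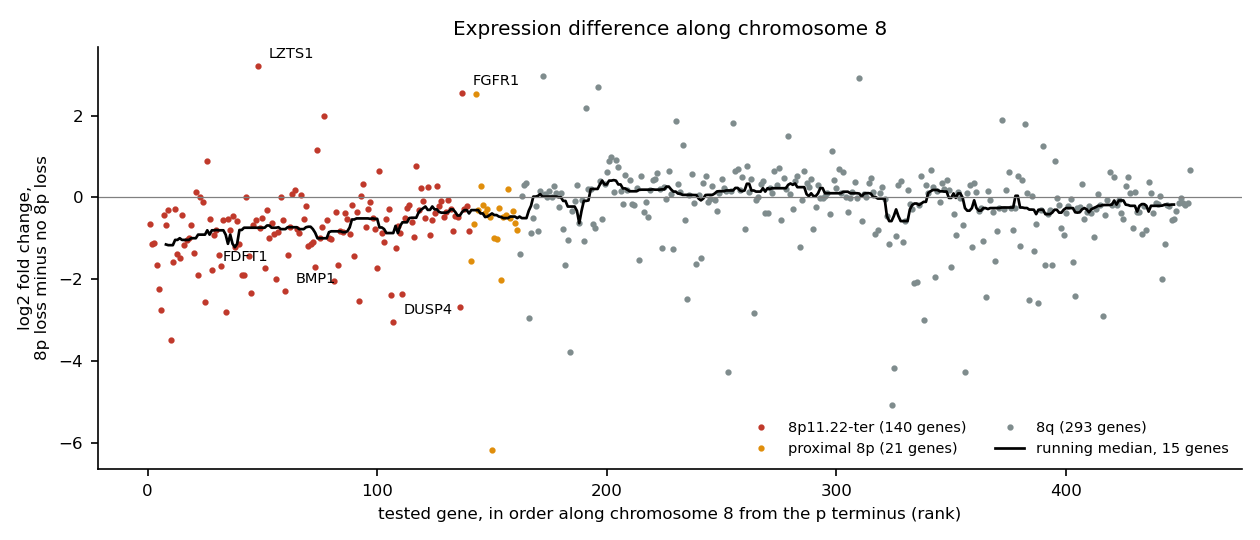
Log2 difference between 8p loss and no 8p loss lines for each tested gene of chromosome 8, in gene order from the p terminus (x axis, rank), with a running median over 15 genes. The 140 genes of 8p11.22-ter have a median of -0.69 and the 293 genes of 8q one of -0.02.

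Over all 23351 features, limma called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.289. At an unadjusted p under 0.05 there were 1916 features, 775 lower and 1141 higher, where chance gives 1168. The lower share was 40.4%, against 27.0% with the authors' matrix values, 28.2% with normexp correction and 61.4% of 1218 features using slide 3 only. Besides FDFT1, the named genes with the smallest p among those lower were FNDC11 at -2.92, JPH2, a junctional membrane protein, at -3.45, and H1-1, a linker histone, at -4.68. FNDC11, JPH2 and H1-1 were lower in all 8 lines with the loss than in every line without it, and H1-1 was well above background in 1 of the 8. CFAP157 was not well above background in any line with the loss and was at least 1.10-fold lower, and it turned to 0.17 with normexp correction. Those higher were CD40, a receptor of the tumour necrosis factor family, at 4.08, FBXO17, an F-box protein, at 5.71, NME4, a mitochondrial nucleoside diphosphate kinase, at 2.22, HDGFL3 at 7.14 and DRC9 at 2.35. FBXO17 and HDGFL3 were well above background in 1 of 4 lines without the loss and CD40 in 2, so their differences rest on signals below background in the others. CD40 was higher in all 8 lines with the loss than in every line without it. None of these passed (limma adjusted p from 0.289 to 0.480). Setting slide 3 against slides 1 and 2, in place of the groups, gave 2738 features past the same limma threshold, and with slide as a fixed block the groups again gave 0, with 2073 at an unadjusted p under 0.05. Without PK-45H, a line without the loss, 3 features passed, HDGFL3 among them (limma adjusted p = 2.6e-05). It was then not well above background in any line without the loss and at least 175-fold higher, and without TCC-Pan2 1 unnamed feature passed.

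Of 24 gene lists, 10 passed limma's camera at an adjusted p under 0.05, 9 toward lower and 1 toward higher expression. With an estimated correlation 0 passed, and by the level per line 5 had an exact permutation p under 0.05 before adjustment and 0 after it. The list of 8p tumour suppressor candidates, all 37 tested members of which lie in the region, had 31 genes lower and 6 higher (camera adjusted p = 1.4e-07; adjusted p = 0.241 with an estimated correlation). Its examples were BIN3, VPS37A, DUSP4 and FBXO25, an F-box protein, at -1.15, and 0 passed adjusted over the list alone. The list's level differed by -0.77 (exact permutation p = 0.00606), by -0.74 under the slide block, and by -0.71, -0.78 and -0.74 within slides 1, 2 and 3.

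Genes of the classical subtype of pancreatic cancer, a secretory and gut-like programme, were lower in the lines with the loss for 23 of 25 members (camera adjusted p = 1.9e-05; adjusted p = 0.241 with an estimated correlation). TFF2 at -4.84 and TFF3 at -3.70, secreted trefoil peptides, passed limma's test adjusted over the list alone (adjusted p = 0.0187 and 0.0289), and 0 passed over all genes. TFF1 at -4.07 and CEACAM5, a cell surface glycoprotein, at -4.49 did not. The level differed by -2.08 (exact permutation p = 0.0404), by -2.16 under the slide block (p = 0.0625, exact permutation), and by -1.94, -3.94 and -0.98 within slides 1, 2 and 3. All 6 tested mucin genes were lower (camera adjusted p = 0.0262; adjusted p = 0.241 with an estimated correlation), with MUC4 at -4.61, MUC16 at -2.07, MUC1 at -2.01 and MUC20 at -1.21. The mucin level differed by -2.30, by -2.08 under the slide block, and by -3.0, -3.62 and -0.23 within the slides. The mucin call ended under the slide block (camera adjusted p = 0.0715) and without each of PK-59, AsPC-1, KP4-1, MIA Paca2 and BxPC-3. MUC20 turned to 1.95 within slide 3 and was -0.38 without AsPC-1, and MUC16 was -0.91 without PK-59.

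All 25 tested epithelial junction and keratin genes were lower (camera adjusted p = 0.000111; adjusted p = 0.572 with an estimated correlation), among them CLDN3, a tight junction protein, at -1.51, ESRP1, a splicing regulator, at -2.81, ST14, a membrane protease, at -3.61 and KRT7, a keratin, at -5.14. The epithelial level differed by -1.75 (exact permutation p = 0.220), by -1.83 under the slide block, and by -2.09, -2.53 and -1.11 within the slides. It was lowest in MIA Paca2 at -3.46 and KP4-1 at -3.38, while PK-1 at 2.72 and PK-9 at 2.97, both with the loss, lay above every line without it. The call ended using slide 3 only (camera adjusted p = 0.0980), and CLDN3 was -0.96 without PK-59. Of the basal-like subtype genes 21 of 23 were lower (camera adjusted p = 0.00133; adjusted p = 0.678 with an estimated correlation), with SLC2A1, a glucose transporter, at -1.51, FGFBP1 at -5.19, AREG, an EGF receptor ligand, at -2.05 and SERPINB3 at -2.96. The basal-like level differed by -1.75 (exact permutation p = 0.352), by -1.49 under the slide block, and by -4.58, -0.30 and -0.07 within the slides. It was highest of all lines in PK-1, with the loss, at 5.37, and PK-9, also with the loss, had 3.86. Without AsPC-1 the call ended (camera adjusted p = 0.373), the level differed by -0.54 and SERPINB3 by -0.81, and the call also ended using slide 3 only (camera adjusted p = 0.904). Integrin and laminin genes were lower for 14 of 19 (camera adjusted p = 0.0491; adjusted p = 0.678 with an estimated correlation), with ITGB8 at -2.96, LAMA3 at -4.01, LAMB3 at -3.70 and LAMB1 at -1.62. The integrin and laminin level differed by -0.84, by -0.91 under the slide block, and by -0.37, -1.37 and -0.97 within the slides. Its call ended without each of 6 lines, with a camera adjusted p of 0.297 and a level of -0.44 without MIA Paca2, where LAMB1 was -0.99. No gene of these 3 lists passed adjusted over the list alone.

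Of the MAP kinase phosphatases, 8 of 10 were lower (camera adjusted p = 0.00473; adjusted p = 0.241 with an estimated correlation). Beside DUSP4 they were led by DUSP10 at -3.06, DUSP7 at -1.12 and DUSP9 at -0.98, and 0 passed adjusted over the list alone. The phosphatase level differed by -1.0 (exact permutation p = 0.0101), by -0.91 under the slide block, and by -0.97, -0.32 and -1.30 within slides 1, 2 and 3. The call ended using slides 1 and 2 only (camera adjusted p = 0.396). Without PK-59, DUSP10 was -1.97 and DUSP9 -0.58. ERK pathway targets and feedback genes did not pass (camera adjusted p = 0.839). Of them 10 were lower and 11 higher, with SPRY1 at 1.56, ETV5 at 1.09, EMP1 at -1.95 and DUSP6 at -2.30, and their level differed by -0.01. SPRY1 was 0.93 without PK-45H, ETV5 0.56 without AsPC-1 and DUSP6 -1.33 without MIA Paca2.

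Markers of other cell types were tested as well. All 6 tested pancreatic acinar markers were lower (camera adjusted p = 0.00473; adjusted p = 0.241 with an estimated correlation), with the trypsinogen genes PRSS2 at -2.95 and PRSS1 at -2.07, RBPJL at -1.12 and CEL at -0.56. The acinar level differed by -1.15 (exact permutation p = 0.0242), by -0.90 under the slide block, and by -0.95, -1.39 and -0.51 within the slides, and the call ended with normexp correction (camera adjusted p = 0.133). All 11 leukocyte markers were lower (camera adjusted p = 0.00473; adjusted p = 0.241 with an estimated correlation), with ITGB2 at -3.53, HCLS1 at -3.26, CD14 at -0.91 and CD2 at -0.82. The leukocyte level differed by -0.54, by -0.28 under the slide block, and by -0.55, -0.48 and 0.07 within the slides. It was -0.32 without PK-59, where CD2 was -0.49, and HCLS1 was -0.88 without AsPC-1. The call ended with probes well above background on all arrays (camera adjusted p = 0.0800). RBPJL, CEL and CD2 turned positive with normexp correction, at 0.17, 0.12 and 0.06.

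Cell cycle genes were higher in the lines with the loss for 24 of 25 members (camera adjusted p = 3.6e-05; adjusted p = 0.241 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, differed by 1.02, E2F1 by 0.79, TOP2A, a DNA topoisomerase, by 0.62 and the cyclin gene CCNB1 by 0.49, and 0 passed adjusted over the list alone. TOP2A was higher in all 8 lines with the loss than in every line without it. The level differed by 0.33 (exact permutation p = 0.0303), by 0.32 under the slide block (p = 0.0521, exact permutation), and by 0.04, 0.49 and 0.39 within slides 1, 2 and 3.

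Other settings ended calls of these lists too. Using slide 3 only, acinar, leukocyte and mucin genes had a camera adjusted p of 0.217, 0.162 and 0.715. With probes well above background on all arrays, basal-like and mucin genes had 0.102 and 0.136, and too few acinar genes remained. Integrin and laminin genes had a camera adjusted p of 0.198 using slides 1 and 2 only and did not pass with array weights either. Some list genes were dim in many lines. Of the 8 lines with the loss, ZEB2 was well above background in 1, SERPINB3, RBPJL, CD2, MUC4 and ANKRD1 in 2, CEACAM5, MUC16, CDH5 and COL3A1 in 3 and ITGB2 in 4. Of the 4 lines without it, COL3A1, MTAP and DMRTA1 were well above background in 2. Of 110 named genes, 35 had a difference that shrank over 1.5 times or turned without 1 of the 12 lines, and these values are given beside them.

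The other 13 lists did not pass camera in the reported fit, with adjusted p from 0.122 upward, and in none of them did a gene pass adjusted over the list alone. Type I interferon response genes were lower for 15 of 21 (camera adjusted p = 0.122), with IRF9 at -0.88, XAF1 at -2.03, OAS1 at -2.67 and IFIT3 at -1.05. Invasion proteases and inhibitors were lower for 14 of 21 (camera adjusted p = 0.148), with CTSB at -0.91, PLAT at -6.16, PLAU at 2.24 (0.87 without PK-59) and ST14 as above. CTSB lies in 8p11.22-ter and PLAT in proximal 8p. Mesenchymal genes divided into 10 lower and 11 higher (camera adjusted p = 0.628, toward lower although the median was 0.05), with ZEB2 at -1.65, SNAI2 at -2.94 and TAGLN at -1.19, while TWIST2, not well above background in any line without the loss, was at least 1.99-fold higher. TGF-beta and YAP targets were lower for 11 of 17 (camera adjusted p = 0.248), with ANKRD1 at -4.14 (-2.64 without PK-59), THBS1 at -2.20, SMAD7 at -1.15 (-0.71 without PK-59) and ID3 at 2.22. Hypoxia and glycolysis genes were lower for 12 of 20 (camera adjusted p = 0.679), with SLC2A1 as above, NDRG1 at -1.56 and PFKFB3 at 0.92. BNIP3, not well above background in any line without the loss, was at least 22.9-fold higher, being well above background in 5 of 8 lines with it. Oxidative phosphorylation genes were higher for 16 of 21 (camera adjusted p = 0.264), with SDHA at -0.92, NDUFB3 at 0.45 (0.23 without PK-59), UQCRFS1 at 0.41 and ATP5PO at 0.35.

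Ribosomal protein genes divided into 14 lower and 16 higher with a median of 0.01 (camera adjusted p = 0.886), among them RPL4 at 0.31, RPL27 at 0.34, RPL8 at -0.34 and RPL32 at -0.30. Immediate early and heat shock genes, with 6 lower and 4 higher (camera adjusted p = 0.628), included FOS at -1.88, HSPA1A at -1.94 (-0.17 without MIA Paca2), DNAJB1 at -0.31 (-0.02 without PK-59) and HSPH1 at 0.23 (0.05 without AsPC-1). Endocrine and neuronal markers, with 8 lower and 3 higher (camera adjusted p = 0.654), included ENO2 at 1.35, INS at -1.24 (-0.23 without PK-59) and NES at -1.13 (-0.50 without PK-45H), and CHGB, not well above background in any line without the loss, was at least 5.31-fold higher. Endothelial markers were lower for 5 of 6 (camera adjusted p = 0.180), with CLDN5 at -1.32 (-0.75 without PK-45H), VWF at -1.34, CDH5 at -1.23 and ESAM at 0.28 (-0.11 without PK-1). Fibroblast and stellate cell markers were higher for 3 of 4 (camera adjusted p = 0.628), with RGS5 at 1.22 (0.43 without MIA Paca2), COL3A1 at 0.90 (0.01 without KP4-1), COL6A3 at 0.21 (-0.17 without BxPC-3) and THY1 at -0.01 (0.14 without PK-45H). Of genes around 9p21, often deleted in pancreatic cancer, CDKN2A differed by -3.03 (-1.81 without BxPC-3), MTAP by 1.78 (0.84 without AsPC-1) and DMRTA1 by 0.80, or -0.13 without PK-45H (camera adjusted p = 0.879, toward lower although the median was 0.80). Of 11 genes around SMAD4 on 18q21, 7 were lower and 4 higher (camera adjusted p = 0.925, toward higher), with ME2 at 2.26, ELAC1 at 2.04, SMAD7 as above and HAUS1 at -0.44. Without AsPC-1, ME2 was 0.67, ELAC1 0.21 and HAUS1 -0.21. Some of these lists passed under other settings. Interferon response genes passed toward lower with slide as a block (camera adjusted p = 0.0114), with normexp correction, with no filter on dim probes, using slides 1 and 2 only, and without TCC-Pan2, PK-45H or PK-59. TGF-beta and YAP targets passed using slide 3 only (camera adjusted p = 1.2e-06) and without PANC-1 and KP-1-NL (camera adjusted p = 0.0214), but pointed toward higher using slides 1 and 2 only, with level differences of 0.95, 0.30 and -1.55 within slides 1, 2 and 3. Endothelial and mesenchymal genes passed toward lower using slide 3 only (camera adjusted p = 0.0304 and 0.0173), where level differences were of the other sign within slide 1 and slide 2 respectively, at 0.43 and 0.90. Invasion genes passed with normexp correction and without PK-45H (camera adjusted p = 0.0108 and 0.0208), and oxidative phosphorylation genes without BxPC-3 (camera adjusted p = 0.0268).

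Genes with only 1 tested probe could not be compared between probes, among them FDFT1, DUSP4, FNDC11, H1-1, CD40, FBXO17, NME4 and HDGFL3. The probes of PFKFB3 and of MTAP disagreed in direction, from -0.70 to 0.92 and from -0.42 to 1.78. Other probes of the same gene gave differences over 1.5 times apart from the printed value for JPH2 at -1.17, DRC9 at 1.11, TFF1 at -2.12, CLDN3 at -2.57, LAMA3 at -1.96, CLDN5 at -0.39, THBS1 at -3.99, HSPA1A at -0.67 and CHGB at 2.35.

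**Figure D3:**
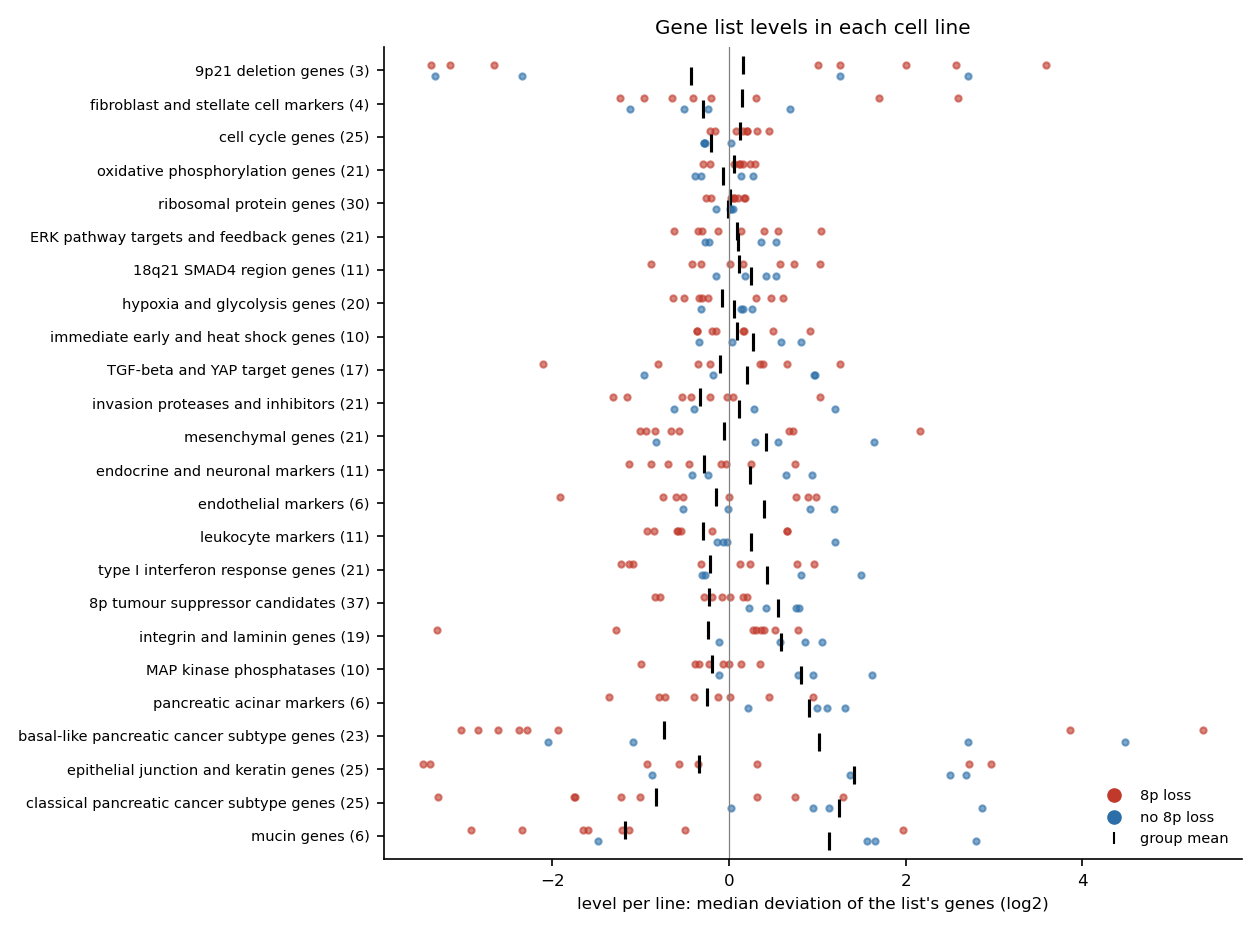
Level of each of the 24 gene lists in each cell line (x axis, median deviation of the list's genes, log2; number of tested genes in parentheses), with lines with the loss in red, lines without it in blue and a bar at each group's mean. Classical subtype genes differ by -2.08 and cell cycle genes by 0.33 between the groups, and the groups overlap in both.

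Among 41 chromosome arms, 8p had the lowest median log2 difference, -0.64 over 161 genes, with a level difference of -0.75 (exact permutation p = 0.0121, Benjamini-Hochberg adjusted p = 0.133). The 99 genes of 5p followed with a median of -0.53 (exact permutation p = 0.0162, adjusted p = 0.133) and the 129 of 20p with -0.43. The highest medians were those of 3q at 0.33 and 2p at 0.32, whose exact permutation p of 0.00808 each was smaller than that of 8p (adjusted p = 0.133), then 17q at 0.32 and 22q and 5q at 0.27 each. An unadjusted exact p under 0.05 was reached by 7 arms and an adjusted p under 0.05 by 0. With slide as a block the level of 8p differed by -0.71 and that of 5p by -0.50.

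**Figure D4:**
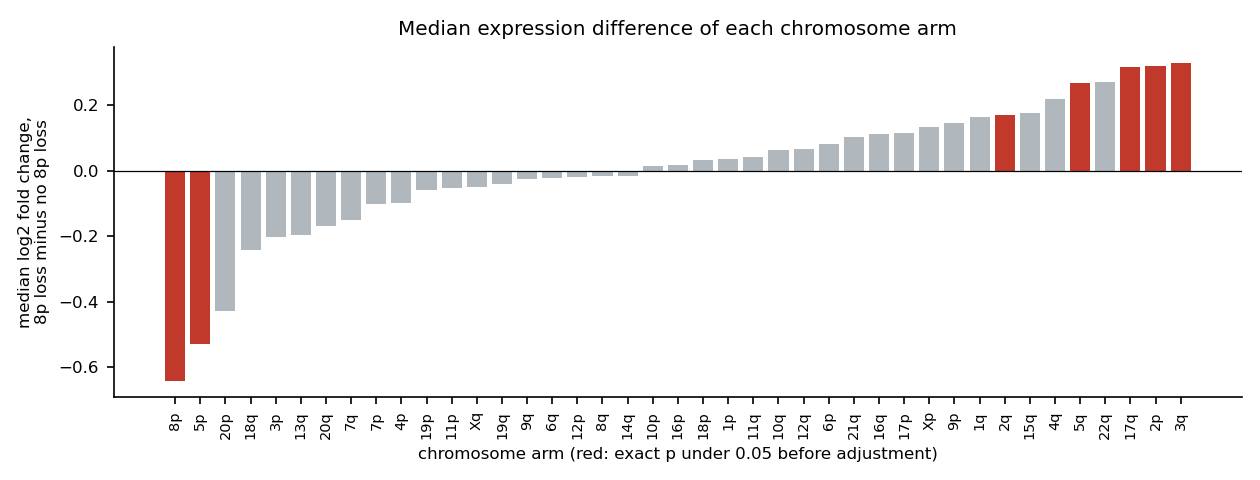
Median log2 difference between 8p loss and no 8p loss lines for the tested genes of each of 41 chromosome arms, in red where the exact permutation p is under 0.05 before adjustment. The 8p arm lies lowest at -0.64 and 3q highest at 0.33.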

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

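The tests of slide and of the similar lines for the region, the tests of the pair PANC-1 and KP-1-NL and the count of splits for genes over the whole genome were chosen after their results, or the values behind them, had been seen. A line was singled out when its gap to the nearest other line of its group was large against the group's range, which chance gives in about 1 of 20 groups. Of 274 groups tested, 20 had such a line, where chance gives 13.7. PK-59 accounts for 5 of them and MIA Paca2 for 4.

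Among the lines without the loss, AsPC-1 had the highest cell cycle level, 0.0213 against -0.27 in the next line. It also had very low signals of 2 genes of 18q21, ME2 at -7.12 and ELAC1 at -8.39, where the next line had -1.11 and -1.48. PK-59 had the highest leukocyte marker level, 1.20, the highest JPH2, -0.11, CEL, -4.63, and CD14, -1.68, and the lowest CCNB1, 3.58. PK-45H had HDGFL3 at 1.34 against -8.02 in the next line, and the lowest ESRP1, -3.84, and ST14, -1.71. BxPC-3 had the lowest KRT7, -1.98, and the highest PRSS2, 4.52. Among the lines with the loss, MIA Paca2 had the highest VPS37A, 0.0146, and the lowest SMAD7, -5.42, HSPA1A, -8.62 against 4.60 in the next line, and DUSP6, -6.35 against 0.02. TCC-Pan2 had the highest TFF2, -0.13, and PK-9 the highest SERPINB3, -1.45, and MUC4, -1.62.

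The lower level of the 8p11.22-ter genes was set against technical explanations. Scaling between arrays would move 8q as well. The region's median minus that of 8q was -0.62 or lower under each of 3 scalings. Percentile scaling and median centring each subtract a constant per array, so that difference cannot vary between them. Of these scalings only quantile normalization could change it, and there it was -0.62. The level difference was -0.74 with slide as a block and -0.61 without PANC-1 and KP-1-NL (exact permutation p = 0.0104 and 0.0143), which argues against either as the whole cause. Of 100 splits of the 12 lines, only the real one gave a -log10 camera p as large, 16.1 against at most 13.1 in the others. Another split reaching 13.1 shows that this camera p cannot be read at face value. Since the 100 were a draw from 495, chance is made unlikely for the group shift but not excluded. Over all 495 splits the region's level gave an exact permutation p of 0.00606. The loss of copies that the labels give stays open as a hypothesis, since copy number was not measured here.

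The higher cell cycle level kept most of its size under slide and without the 2 similar lines, but its exact p missed 0.05 in both, so neither was excluded. It was 0.33 (exact permutation p = 0.0303), 0.32 with slide as a block (p = 0.0521, exact permutation) and 0.31 without PANC-1 and KP-1-NL (p = 0.0619, exact permutation). Camera at its preset correlation passed in both (adjusted p = 0.00107 and 0.000129).

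The lower classical subtype level likewise kept most of its size with an exact p over 0.05 in both, and neither was excluded. It was -2.08 (exact permutation p = 0.0404), -2.16 with slide as a block (p = 0.0625, exact permutation) and -1.91 without PANC-1 and KP-1-NL (p = 0.114, exact permutation). Camera at its preset correlation passed in both (adjusted p = 1.2e-05 and 0.000129).

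Chance was not excluded for 3 other counts, and the real grouping is among the splits counted for each. A single region gene or more was called lower in the larger group in 7 of 100 splits, with 4 at most. Setting slide 1, 2 or 3 against the others called 1, 3 and 11 region genes higher on that slide in the same form of fit. The groups with slide as a block gave 2 lower in the lines with the loss. The 10 gene lists were reached by 7 splits, with 14 at most. The 1916 genes at an unadjusted p under 0.05 were reached by 17 splits, with 4085 at most, and setting slide 1, 2 or 3 against the others gave 2467, 2025 and 4596, each above the 1916 of the groups in the same form of fit. With slide as a block the groups gave 2073. For the count of 0 genes past the adjusted limma threshold the splits decide nothing, as all 100 give 0 or more. Of them, 23 gave 1 or more genes, with 543 at most. The split with 543 set KP4-1, MIA Paca2, PANC-1 and KP-1-NL against the rest, all 4 of them lines with the loss, and setting slide 3, scanned on another day, against the others gave 2738. Both point to a structure of the samples, the first within the lines with the loss, and slide 3 cannot be told apart from the lines it holds. The 4 lines of the first split also had the lowest DUSP4 of all lines, from -3.44 in PANC-1 to -1.32 in KP-1-NL.

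PANC-1 and KP-1-NL had a correlation of deviations of 0.717, where the other 17 pairs on 1 slide had at most 0.256. Between them, 91 of 4394 genes with 2 or more probes differed over 4-fold with every probe in the same direction, which argues against one RNA on 2 arrays.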

How the results depend on the processing

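The averaging of PANC-1 and KP-1-NL, leaving both out, and using slides 1 and 2 only were chosen after seeing the data. No paired analysis was possible because each cell line belongs to a single group and the replicate numbers only count the lines. The set test of the region kept its direction and its side of the threshold under all 29 alternatives that gave it, with camera p from 1.4e-21 to 3.5e-10 with each line left out in turn. The level of the region kept its direction throughout, from -0.95 to -0.68 with each line left out, and was smallest with normexp at -0.53 (exact permutation p = 0.0424). DUSP4 kept its direction and stayed short of the limma threshold over all genes under 27 alternatives, from -3.40 to -2.66 with each line left out. Its difference was smaller without both PANC-1 and KP-1-NL, at -2.49 (limma adjusted p = 0.833), and using slides 1 and 2 only, at -2.57 (limma adjusted p = 0.910). Of the named genes, 3040 values kept direction and side, 28 now passed, 2 no longer did and 41 changed sign. The random block gave no camera or level value, array weights and trend with robust no level value. Signal over background limits how far the folds of dim genes can be read.

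The level was -0.71 using slide 3 only and -0.62 using slides 1 and 2 only, and no longer passed, where only 6 and 28 splits exist. The count of region genes adjusted over the list alone was 1 in the reported fit, 7 of 99 with probes well above background on all arrays, 2 with slide as a fixed block (FDFT1 and ZNF395), 8 with array weights and 0 using slides 1 and 2 only, where FDFT1 was -1.75, and 1 to 5 with each line left out. Using slide 3 only it was 2, FAM167A at least 5.61-fold lower and DPYSL2 at -6.28, and DPYSL2 was 0.99 using slides 1 and 2 only. Of 10 gene lists past camera, 6 stayed with probes well above background on all arrays and 0 with an estimated correlation, and 7 to 12 passed with each line left out. The count over all genes was 0 in the reported fit, 0 to 3 with each line left out, and 2 using slides 1 and 2 only (MAP2K4 at least 281-fold and HDGFL3 at least 177-fold higher, neither well above background in any line without the loss there). The 3 without PK-45H were HDGFL3, KRABD3 at 5.13 and 1 unnamed feature. MAP2K4, KRABD3, FAM167A and DPYSL2 were named after their values were seen. The lower share of genes at an unadjusted p under 0.05 was 40.4%, and 28.2% with normexp and 27.0% with the authors' matrix, where the median over all genes was 0.13 and 0.10, and 61.4% using slide 3 only. Beyond fewer lines or genes tested, the cause was not tested.

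These genes changed sign, and the cause was not tested. With normexp, CFAP157 was 0.17, RBPJL 0.17, CEL 0.12, CD2 0.065, CDH5 0.10 and ZEB2 0.011. THY1 was 0.043 with median centring, 0.12 with the authors' matrix, 0.23 and 0.065 with slide as a fixed and random block, 0.00065 with the pair averaged and 0.016 without it. ESAM was -0.11 with the fixed block and COL6A3 -0.020 with array weights. Using slide 3 only, LOXL2 was -2.15, ESRP1 0.31, CEL 0.39, MUC20 1.95, VWF 0.46, ESAM -1.62, COL6A3 -0.085, THY1 0.61, TAGLN 0.15, HSPH1 -0.48, ENO2 -0.082 and HAUS1 0.090. INS was 0.10 using slides 1 and 2 only. With each line left out, ESAM ranged from -0.11 to 0.59, COL6A3 from -0.17 to 0.55, THY1 from -0.17 to 0.14 and DMRTA1 from -0.13 to 1.88.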

Other observations

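The list of sterol genes and the tests below were written after the largest single differences had been seen, and the correlation of DUSP4 with the level of the region was chosen after its values had been seen. HMGCS1, MSMO1, CYP51A1 and INSIG1 were named after their values were seen.

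Beside FDFT1, other genes of cholesterol synthesis and uptake were lower in the lines with the loss. HMGCS1, which makes the precursor of mevalonate and lies on 5p, differed by -2.06 (SE 0.39). MSMO1 differed by -1.26 and CYP51A1, both enzymes of the late pathway, by -0.79. INSIG1, a sterol sensor, differed by -1.16, and none of the 4 passed over all genes (limma adjusted p from 0.456 to 0.504). With FDFT1 and HMGCS1 left out, 19 of 23 genes of the list were lower, with a median of -0.62. Camera with an estimated correlation gave p = 0.0194. The level per line was -0.17 ± 0.24 (SD, n = 8) against 0.36 ± 0.39 (SD, n = 4), a difference of -0.53 (exact permutation p = 0.0182), and 4 of the 8 lines with the loss lay below every line without it. With slide as a block camera gave p = 0.0262 and the level differed by -0.45 (exact permutation p = 0.0521). Within slides 1, 2 and 3 it differed by -0.42, -0.07 and -0.77, and with each line left out in turn by -0.70 to -0.42, with an exact permutation p up to 0.0667. The values are consistent with a hypothesis that sterol synthesis genes are set lower together in these lines with the loss, rather than FDFT1 alone. How the lines were cultured could also set these genes, which was not tested.

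DUSP4 was compared with other measures over the 12 lines, in a family of 3 relations. Against the ERK target level Pearson's r was 0.25 (permutation p = 0.441, Benjamini-Hochberg adjusted p = 0.441) and Spearman's rho 0.27 (permutation p = 0.392), and r was 0.25 without the 2 lines farthest from the median of DUSP4. The hypothesis that ERK targets are higher where DUSP4 is lower, which needs a negative r, was therefore not borne out. This concerns transcript levels across lines only. ERK activity was not measured, so an effect of DUSP4 on it was not tested. Against the level of the other region genes r was 0.71 (permutation p = 0.00956, adjusted p = 0.0287) and rho 0.69 (permutation p = 0.0154), with r = 0.79 without the 2 farthest lines. Within the 8 lines with the loss r was 0.33 (exact permutation p = 0.406), so the relation over all lines may rest on the difference between the groups. Against DUSP6, a relation added after its values were seen, r was 0.59 (permutation p = 0.0294, adjusted p = 0.0441) and rho 0.69 (permutation p = 0.0178). Without the 2 farthest lines r was 0.37. Within the 8 lines with the loss r was 0.48 (exact permutation p = 0.225), while rho stayed at 0.69 (exact permutation p = 0.0694). Whether this relation too rests on the difference between the groups is therefore left open.

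The shift was tested for a difference along the region. The 70 distal genes had a median of -0.82 and the 70 proximal ones of -0.52, and their levels differed between the groups by -0.90 and -0.70. The difference of the distal minus the proximal level, -0.20, did not pass (exact permutation p = 0.162). The 5p arm, which holds HMGCS1 and SDHA, had the next lowest median of all arms after 8p.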
